A study of Mus musculus with 2 samples.

How the data were processed

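Polyadenylated RNA of inflammation-experienced regulatory T cells was sequenced. Per the labels, these were primary cells of male mice aged 7 weeks that had come from activated regulatory T cells, and the RNA libraries were fragmented by shearing to a size range of 100 to 300. Regulatory T cells are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. The labels give 1 biological replicate with 2 technical replicates, called library 1 and library 2 here, and name no other condition. The 2 libraries therefore formed 1 group, no test between conditions was possible, and SDs between them (n = 2) measure the difference between 2 libraries of 1 biosample, which may include differences between RNA preparations or in cell composition, and do not measure spread between animals.

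The large gene table and the transcript table of each library hold expected counts, TPM and FPKM that the authors derived from alignments to the transcriptome (mm10, GENCODE M21), per the deposited description. Expected counts are estimates that share reads mapping to several genes among them, per the file headers. TPM values were scaled by the authors to a common sum per library using effective length. FPKM values were divided by the authors by effective length and total reads, per the file headers. The transcript table also holds the percent of a gene in each transcript, per the file headers. The small gene table holds whole-number counts that the authors derived from an mm10 alignment with GENCODE M4, per the deposited description. The aligner, the quantifier and any removal of duplicate reads are not given in the sources used here.

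Each large table listed 81881 rows, of which 55536 were GENCODE genes, 26248 had a bare number as identifier and 97 were spike-in sequences. All 55536 gene identifiers were found in the GENCODE M21 annotation, which gave symbols, gene types and mm10 coordinates. The bare-number and spike-in rows were left out of library totals and tests. They held 2347 and 51295 counts (bare-number rows and phiX174) of library 1, and 3761 and 48064 of library 2. Each small table listed 22457 genes, of which 22195 were matched by identifier.

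Library 1 held 26593267 expected counts over GENCODE genes and library 2 held 22036331. The small tables held 7911181 and 6972139 counts. A count of 0 allows up to 3 counts, which is a CPM of 0.113 in library 1 and 0.136 in library 2. Intervals of shares are 95% Wilson intervals. Intervals, floors and the binomial test cover counting error only, because copies made by PCR are not independent molecules. Strand use in counting is not stated, so overlapping and antisense genes are uncertain, as are genes with near-identical copies.

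A gene was called detected at a TPM of at least 1 in both libraries. Expected counts were rounded to whole numbers and compared gene by gene with a 2-sided exact binomial test against the share of each library in the total, for genes with at least 10 counts summed over both, with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. This test compares these 2 libraries, not conditions. Ratios are library 2 over library 1 of counts divided by library totals, after adding 0.5 counts. A fold against 0 counts was computed with 3 counts in that library and is given as a lower bound. The coefficient of variation between the libraries was the square root of the common dispersion from edgeR 4.0.16 (R 4.3.3), with filterByExpr and TMM factors. Correlations were taken across genes on log2(TPM + 1), and genes are not independent replicates.

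Before the data were examined, 22 gene lists with 246 distinct genes were fixed, with the tests, the alternatives and a rule for the genes to name. The rule took the 4 members of each list with the highest mean TPM, up to 4 members under a TPM of 1 in either library, Foxp3, and for lists of other cell types up to 4 members at a TPM of 1 or above in both. It also took the 15 most abundant genes that are neither mitochondrially encoded nor ribosomal protein genes, and the 5 genes with the largest ratio in each direction among those called with at least 100 counts. Of the genes taken by this rule, 3 are not reported here. Isoforms were described for 15 genes. Other genes named were chosen after their values were seen. The median log2 ratio of each list, on TPM + 1, was placed among 10000 random lists of the same size drawn from genes within 100 ranks in mean expression. Alternatives were TMM scaling, DESeq2 1.42.0 size factors, other thresholds and pseudocounts, FPKM, the small table, and each library alone. A further 8 lists were written after the data had been seen.

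The binomial test was checked on simulated counts for 55536 genes with the means and sizes of these libraries. It recovered 82 of 100 genes changed 1.5-fold and 91 of 100 genes changed 2-fold, called 4 unchanged genes, and gave a chi-square over degrees of freedom of 0.999. The changed genes all had at least 100 expected counts over both libraries, and counts in this check varied by counting error only. The real libraries differed by more (chi-square over degrees of freedom 33.5), so these rates do not carry over to them. Changed genes with fewer counts were not covered. A simulated coefficient of variation of 0.2 was recovered as 0.197. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.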

Results

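The 2 technical libraries of inflammation-experienced regulatory T cells held 26593267 and 22036331 expected counts over GENCODE genes. Protein-coding genes took 94.9% of the counts in library 1 (95% interval 94.87 to 94.89) and 94.7% in library 2 (94.74 to 94.76). Mitochondrially encoded genes took 1.64% (1.638 to 1.648) and 1.63% (1.623 to 1.634). Ribosomal protein genes took 2.57% (2.565 to 2.577) and 2.26% (2.255 to 2.267). The 10 most abundant genes took 4.39% (4.380 to 4.396) and 4.33% (4.324 to 4.341).

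The first question was which genes this cell population transcribed. At a TPM of at least 1 in both libraries, 13718 genes were detected, and 10818 of them were protein-coding. Library 1 alone had 15359 such genes and library 2 alone had 19186. The most abundant transcript was Tmsb4x, an actin-binding peptide, at a TPM of 14644 ± 247 (SD, n = 2 technical libraries). The class I major histocompatibility genes followed, with H2-K1 at 9729 ± 254, B2m at 6210 ± 448 and H2-D1 at 5124 ± 470. The reads of H2-K1 and H2-D1 are hard to tell apart because the genes are close copies. The other abundant genes were Eef1a1 at 4109, Tmsb10 at 3942, Pfn1 at 3668, the T cell receptor constant gene Trbc2 at 3571, Ppia at 3524, Malat1 at 3464 and Cfl1 at 3103. An rRNA gene (CT010467.1, 5528), Gm37376 (4702) and the uncertain copies Gm29216 (4196) and Gm12918 (3276) completed the 15. Gm37376 lies within Malat1 on the opposite strand, so its reads may not be told apart from those of Malat1.

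T cell identity genes were near the top of the range. All 12 members were detected, with a median TPM of 546, at the 98.3 percentile of detected genes. Lck, the kinase bound to CD4, stood at 1228 ± 12.3, Cd3g at 1163 ± 3.12, Cd3e at 1084 ± 54.4 and Cd2 at 813.5 ± 3.54 (SD, n = 2). Between the libraries, 2 of the 12 were higher in library 2, 3 were higher in library 1 and 7 did not pass the test. With TMM scaling 1 was higher in library 2 and 7 in library 1. Adjusted over the list alone, 5 were called.

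All 14 members of the regulatory T cell core list were detected. Foxp3, the factor that defines the lineage (chromosome X, 7573644 to 7595245, plus strand, mm10), stood at a TPM of 87.3 ± 0.0849 (SD, n = 2), at the 83.3 percentile of detected genes. Its count ratio was small but called, with a log2 ratio of -0.08 (adjusted p = 0.0329, exact binomial test), a call lost in the small table (-0.04). The highest members were the folate receptor relative Izumo1r at 411 ± 98.4, Tnfrsf18 (GITR) at 357 ± 17.7, Capg at 307 ± 17.4 and Tnfrsf4 (OX40) at 272 ± 55.9. Of the 14 members, 10 were higher in library 1 and 3 in library 2. Adjusted over the list alone, 13 were called. The median log2 ratio of the list was -0.22, at the 0.45 percentile of random lists. The median log2 ratio of counts was -0.27, and -0.08 in the small table, and the erythroid or platelet, B cell and CD8 T cell lists were lower in library 2 too. Lrrc32, which holds latent TGF-beta on the surface, was 1.96-fold higher in library 1, and Socs2 was 2.15-fold higher in library 2.

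**Figure D1:**
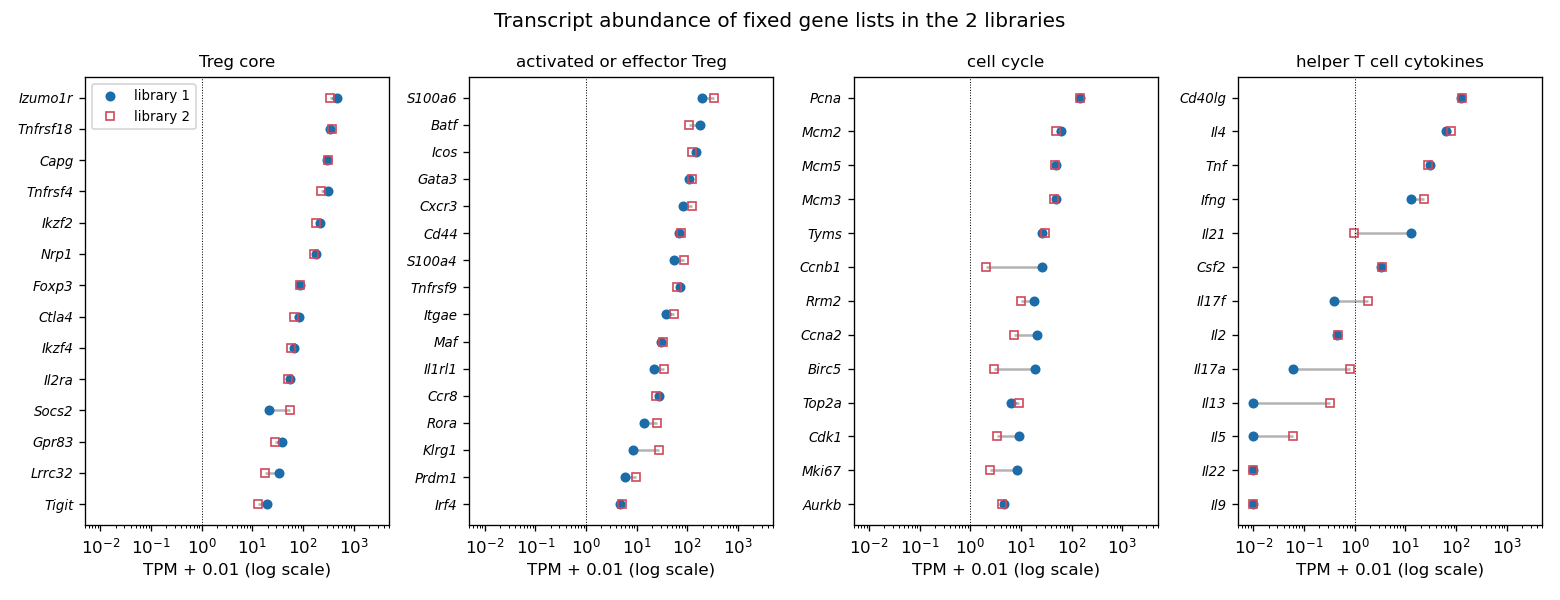
Transcript abundance (TPM + 0.01, log axis) of 4 fixed gene lists, 1 row per gene, with library 1 as filled circles and library 2 as open squares joined by a grey line, and a dotted line at a TPM of 1. All 14 core genes and all 13 cell cycle genes lie above the line in both libraries, and 5 of the 13 cytokine genes do.

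Genes of resting or central cells were abundant beside genes of effector cells. All 12 resting genes were detected at a median TPM of 317, among them Tcf7 at 1053 ± 75.9, Klf2 at 503 ± 85.1 and Ccr7 at 462 ± 3.10 (SD, n = 2). In the resting list 6 genes were higher in library 2, 3 in library 1 and 3 did not pass, with 9 called when adjusted over the list alone. With TMM scaling 5 were higher in each library. All 16 genes of activated or effector cells were detected too, at a median TPM of 56.4. Its highest members were S100a6 at 268 ± 104, Batf at 144.5 ± 53.6, Icos at 137 ± 17.0 and Gata3 at 115 ± 12.5. In this list 10 genes were higher in library 2 and 4 in library 1, with 14 called when adjusted over the list alone. Its median log2 ratio of 0.38 lay at the 99.99 percentile of random lists. The median log2 ratio of counts was 0.35, and 0.28 in the small table. The NK cell list, at the 99.05 percentile, and 2 macrophage lists written after the data were seen were higher in library 2 too. The inhibitory receptor Klrg1 was 3.18-fold higher in library 2, and Batf was 1.75-fold higher in library 1.

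Of 12 suppressor molecules, 10 were detected. The ectonucleotidase Nt5e (123 ± 4.16), Tgfb1 (117 ± 18.4), the checkpoint receptor Pdcd1 (102 ± 64.0) and Entpd1 (36.8 ± 6.70) had the highest TPM. Il12a had 0 counts in both libraries, and Areg stood at a TPM of 0.52 and 2.84. Pdcd1 was 2.62-fold higher in library 1 (log2 ratio -1.39, and -0.80 in the small table). Il10 was 2.56-fold higher in library 1, a call lost in the small table, where the log2 ratio was -0.53. In this list 4 genes were higher in library 2 and 5 in library 1, and 9 were called when adjusted over the list alone.

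Most helper T cell cytokines were low. Of 13 members 5 were detected in both libraries, and 8 were at a TPM threshold of 0.1. Cd40lg at 129 ± 2.18, Il4 at 72.2 ± 13.5, Tnf at 29.3 ± 1.89 and Ifng at 18.3 ± 7.16 were the highest (TPM, SD, n = 2). Il9 and Il22 had 0 counts in both libraries. Il5 had 0 and 1 counts, and Il13 had 0 and 5. Among the 9 members tested, 4 were higher in library 2 and 1 in library 1, and 5 were called when adjusted over the list alone. The follicular helper cytokine Il21 was the one higher in library 1, 12.6-fold, with 615 and 40 counts. With TMM scaling 2 members were higher in library 1.

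All 35 T cell transcription factors were detected. Tcf7 (1053), Ets1 (807), Id2 (675) and Klf2 (503) had the highest mean TPM. Of the 35, 15 were higher in library 2 and 14 in library 1, with 29 called when adjusted over the list alone. Tbx21 (T-bet), the factor of type 1 responses, had a TPM of 10.3 in library 1 and 40.8 in library 2, a 3.93-fold difference. Foxp3 (87.3) is a member of this list as well.

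Homing receptors (19 of 20 detected) were led by Itgb7 at 1056 ± 110, Selplg at 766 ± 78.2 and Itgb1 at 606 ± 117. Ccr10 stood at a TPM of 0 and 0.57. In this list 10 genes were higher in library 2 and 5 in library 1, and 15 were called when adjusted over the list alone. Cxcr5, which guides cells to follicles, was 3.35-fold higher in library 1, and Ccr2 was 1.91-fold higher in library 2. Cytokine receptors (18 of 20 detected) were led by Il2rg at 1328 ± 108, Il2rb at 295 ± 2.55, Il7r at 293 ± 43.3 and Il27ra at 292 ± 7.99. Il12rb2 stood at a TPM of 0.61 and 0.85, and Il1r1 had 276 counts in library 1 and 1 in library 2. Here 7 genes were higher in library 2 and 4 in library 1, and 11 were called when adjusted over the list alone.

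Interferon-stimulated genes (13 of 14 detected) included Irf1 at 338 ± 19.6, Gbp4 at 187 ± 0.530 and Bst2 at 102 ± 4.41. Ifi44 stood at a TPM of 0.02 and 1.37. Of the 14, 7 were higher in library 2 and 3 in library 1, and 10 were called when adjusted over the list alone. Irf7 was 2.02-fold and Ifit3 2.26-fold higher in library 2. The 12 immediate early genes were all detected, led by Junb (676 ± 196), Hspa1b (648 ± 127), Jund (530 ± 105) and Zfp36 (311 ± 91.6). In that list 9 were higher in library 2 and 2 in library 1, and 11 were called when adjusted over the list alone. Its median log2 ratio was 0.40, at the 100 percentile of random lists. The median log2 ratio of counts was 0.38, and 0.21 in the small table. As for the effector list, NK cell and macrophage genes were higher in library 2 too. Hspa1a and Hspa1b are near-identical copies and their split is uncertain.

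Cell cycle genes were higher in library 1. Pcna stood at 146 ± 2.44, Mcm2 at 56.3 ± 8.78, Mcm5 at 48.5 ± 1.92 and Mcm3 at 47.0 ± 2.67, and all 13 members were detected. Of the 13, 10 were higher in library 1 and 2 in library 2, with 12 called when adjusted over the list alone, and the median log2 ratio of -0.31 lay at the 0.87 percentile of random lists. The median log2 ratio of counts was -0.94, and -0.79 in the small table. The largest ratios in the list were those of Ccnb1 (cyclin B1), 24.9-fold (log2 ratio -4.64, and -3.40 in the small table), Birc5, 5.36-fold, and Mki67, 4.33-fold higher in library 1, while Top2a and Tyms were 1.19-fold higher in library 2. Neither exception held in the small table, where Top2a was not called and Tyms had a log2 ratio of -0.05. At a TPM threshold of 5, 8 of the 13 were detected. Globin transcripts were higher in library 1 too, at 0.278% of counts against 0.00304%.

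Glycolysis genes (14 of 15 detected) were led by Ldha at 939.5 ± 25, Eno1 at 891 ± 37.5, Aldoa at 677 ± 49.8 and Pkm at 592 ± 4.39. Hk2 stood at a TPM of 0.93 and 2.01. In this list 7 genes were higher in each library, and 14 were called when adjusted over the list alone. NF-kappaB pathway genes were detected for all 12 members, led by Nfkbia at 368 ± 18.6, Traf1 at 227 ± 31.1, Ikbkb at 192 ± 9.62 and Rela at 143 ± 1.51. Of these, 5 were higher in library 2 and 2 in library 1, and 7 were called when adjusted over the list alone. Housekeeping genes were led by B2m, Ppia, Actb (2019 ± 34.8) and Ywhaz (762 ± 26.1). All 8 housekeeping genes were higher in library 1, with a median log2 ratio of -0.09, and all 8 were called when adjusted over the list alone. Their median log2 ratio of counts was -0.14, and 0.05 in the small table.

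Transcripts of other cell types were present and differed between the libraries. Of the erythroid or platelet list, 6 of 8 genes were detected and 6 were higher in library 1. Hbb-bs, an adult beta-globin gene (chromosome 7, 103826534 to 103828096, minus strand, mm10), had a TPM of 2971 in library 1 and 44.6 in library 2. Hba-a2 had 2993 and 29.3, Hba-a1 had 1787 and 10.95, and Hbb-bt had 678 and 8.72. The globin genes are close copies, and together they took 0.278% of counts in library 1 (95% interval 0.276 to 0.280) and 0.00304% in library 2 (0.00281 to 0.00327). The median log2 ratio of this list was -6.03, at the 0 percentile of random lists. The difference was smaller in the small table, where the median log2 ratio of counts was -2.45, against -6.69 in the large table, and where Hbb-bs had 190 and 27 counts. Adjusted over the list alone, 6 were called.

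Of the B cell list, 7 of 8 genes were detected, with Ighm at 442 ± 7.65, Igkc at 229 ± 25.8, Cd79b at 54.0 ± 15.8 and Cd79a at 48.4 ± 11.1 (TPM, SD, n = 2). In this list 6 were higher in library 1 and 1 in library 2. The CD8 T cell genes Cd8b1 (24.3 and 13.1) and Cd8a (2.73 and 0.37) were both higher in library 1, at the 1.19 percentile of random lists. In the NK cell list 3 of 6 genes were detected, namely Nkg7 (193 ± 56.4), Klrk1 (52.2 ± 28.3) and Klrb1c (4.01 ± 0.361), and 3 were higher in library 2, at the 99.05 percentile. Of 9 myeloid genes 3 were detected, namely Lyz2 (23.8 and 3.72), Fcgr3 (2.13 and 3.27) and Adgre1 (1.19 and 2.64). There 5 were higher in library 2 and 3 in library 1, at the 40.96 percentile, with 6 detected in library 2 alone. Of the dendritic cell list Xcr1 (2.41 and 2.24), Zbtb46 (2.80 and 1.74) and Flt3 (1.00 and 1.44) were detected. There 1, Flt3, was higher in library 2 and 2 in library 1, but Flt3 had 48 and 3 counts in the small table. The stroma or epithelium genes Pecam1 (83.2 and 76.4) and Epcam (9.84 and 5.43) were detected and were the 2 of 6 higher in library 1. The 4 higher in library 2, namely Col1a1, Col3a1, Krt8 and Krt18, were not detected in both libraries. Adjusted over each list alone, the calls were 7 for B cell, 2 for CD8 T cell, 3 for NK cell, 8 for myeloid, 3 for dendritic cell and 6 for stroma or epithelium.

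The second question was how far the 2 technical libraries differed. Of 24253 genes tested, 17040 passed an adjusted p of 0.05 in the exact binomial test, 11255 higher in library 2 and 5785 higher in library 1. At least 2-fold differences were found for 7523 genes in library 2 and 2021 in library 1. With DESeq2 size factors the split was 9468 and 7794, because the median log2 ratio of detected genes moved from 0.01 to -0.14. Chi-square over degrees of freedom was 33.5, so the libraries differed by more than counting error and were not counted as 1 sample. The small table gave 16.1 and 7831 calls. Copies made by PCR may raise the chi-square, so it does not by itself show a difference in RNA. Abundant genes differed less. The median absolute log2 ratio was 0.29 for detected genes and 0.16 for the 3982 genes at a mean TPM of at least 50, of which 22 were at least 2-fold higher in library 1 and 12 in library 2. Among genes with at least 100 counts, 1139 were at least 2-fold higher in library 2 and 634 in library 1. Small differences depended on the table. Of 182 called members of the fixed lists tested in both tables, 21 had the opposite sign in the small table, and 8 of these were called there. All 21 were under 2-fold in the large table. This limit did not hold in the small table, where Flt3 had a log2 ratio of -3.61 instead of 0.59.

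Ranked by the ratio after the small count was added to each library, the largest differences involved genes with 0 counts in one library. This order depends on the count added, and the lower bounds given here do not keep it. Alas2, with 1877 and 9.19 counts, was 164-fold higher in library 1, above every bound given for that library except that of Aqp1. Sirpa, with 3 and 286 counts, was 98.8-fold higher in library 2, above the bounds of Bcar1, C1qc and Gm6565. In library 1, Aqp1, a water channel (chromosome 6, 55336432 to 55348555, plus strand), was at least 264-fold higher (956 and 0 counts). The uncertain pseudogene Gm6361 (at least 55.3-fold), the centromere gene Cenpi (at least 49.7-fold) and Cldn13 (at least 48.3-fold) followed. In library 2, Trf (transferrin, chromosome 9, 103204001 to 103230444, minus strand) was at least 156-fold higher in the large table, but had only 0 and 8 counts in the small table. Fcna (chromosome 2, 25624666 to 25628030, minus strand) was at least 103-fold, Bcar1 at least 90.5-fold and the complement gene C1qc at least 89.7-fold higher, with 209, 102 and 158 counts in the small table of library 2 and 0 in that of library 1. The pseudogene Gm6565, with uncertain reads, was at least 89.6-fold higher.

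**Figure D2:**
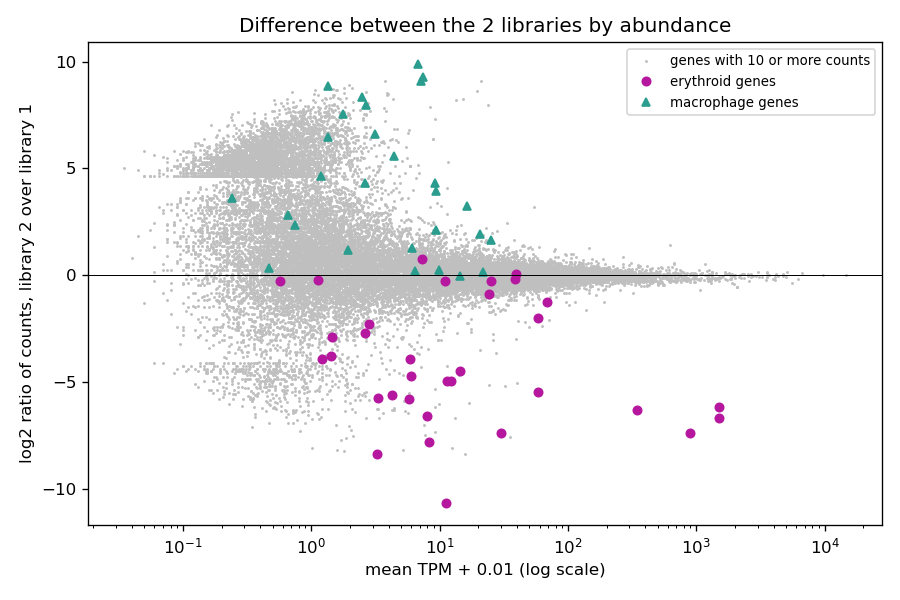
Log2 ratio of counts, library 2 over library 1, against mean TPM + 0.01 (log axis) for genes with at least 10 counts, with erythroid genes as circles and macrophage genes as triangles, both from lists written after the data were seen. Aqp1 lies lowest and Trf highest, and both had 0 counts in one library, so their positions depend on the 0.5 counts added.

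Across 55536 genes the Pearson correlation of log2(TPM + 1) was 0.959 (95% interval over resampled genes 0.958 to 0.960) and the Spearman correlation of TPM was 0.766. The coefficient of variation between the libraries was 0.353 over 15356 genes. It was 0.150 from the median of dispersions estimated by DESeq2 per gene, and 1.02 with no filter. Small and large gene tables of the same library had a Pearson correlation across genes of 0.950 in library 1 and 0.933 in library 2, with Spearman values of 0.940 and 0.931.

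Isoform shares were described for 15 genes, and the same transcript was the most abundant in both libraries by TPM for 15 of 15. The median share of that transcript was 62.4% of TPM. These are model estimates, and which transcript leads depends on the measure. Expected counts, which are not divided by length, put the same transcript first in both libraries for 11 genes, in one library for Foxp3 and Ikzf2, and in neither for Ikzf4 and Cd44. For Foxp3, a protein-coding transcript with 12 exons took 50.9% and 58.5% of TPM, and another with 13 exons and the same 1287 coding bases took 31.7% and 24.4%. The leading Ctla4 transcript took 99.0% ± 1.39 (SD, n = 2). Cd44 was divided between a transcript with 9 exons (49.4% ± 3.03) and another with 14 exons (45.5% ± 1.94 of TPM), which led by expected counts in both libraries. The leading transcript of Il1rl1, the IL-33 receptor, took 55.2% and 69.5%. Ikzf2 and Ikzf4 differed in kind. The leading Ikzf2 transcript was annotated as a retained intron (72.1% ± 1.68 of TPM, but 46.6% of expected counts), and the leading Ikzf4 transcript as subject to nonsense-mediated decay (52.0% ± 0.577 of TPM). By expected counts a protein-coding transcript led for Ikzf4 in both libraries and for Ikzf2 in library 1. The leading shares were 67.3% for Il2ra, 34.0% for Ptprc, 78.3% for Il7r, 75.9% for Tcf7, 51.2% for Lef1, 50.6% for Tnfrsf18, 60.0% for Icos, 86.4% for Batf and 80.3% for Prdm1.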

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

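The tests of a single pool of RNA, of amplification, of protein-coding genes on chromosome X, of sequencing depth, of counting by position and of another cell type without a limit in library 2 were chosen after their results had been seen. Signal in data outside the comparisons was found on the spike-in row of phiX174, with 51295 counts in library 1 and 48064 in library 2, above the 3 counts that a count of 0 allows. Rows with a bare number as identifier held 2347 and 3761 counts. The ERCC spike-in rows held 0 counts in both libraries.

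Erythroid transcripts were higher in library 1 and macrophage transcripts in library 2. The fixed erythroid or platelet list had a median log2 ratio of -6.03, at the 0 percentile of random lists. This gap was seen before the test of a single pool of RNA was chosen, so the test is no independent support. The values argue against equal content of the 2 libraries, and do not tell at which step the difference arose. Amplification of a few molecules as the only source is argued against too, since it acts gene by gene, while the 17 erythroid genes not looked at before moved together. Their median log2 ratio on TPM + 1 was -0.84, at the 0 percentile of random lists. Of the 16 tested, 12 were higher in library 1 and 1, whose sign turned in the small table, in library 2. Whether amplification enlarged the difference cannot be told from the 2 gene tables. The median log2 ratio of counts of the fixed list was -2.45 in the small table and -6.69 in the large table. The small table levels off at abundant genes and keeps fewer reads of genes with uncertain counts, as given below. Either could shrink the ratio of the globin genes, which are close copies. The genes not looked at before had a median of -1.30 in the small table. RNA of macrophages in library 2 may contribute. The 19 macrophage genes not looked at before had a median log2 ratio of 1.24 on TPM + 1, at the 100 percentile of random lists. Their median log2 ratio of counts was 2.24 over the 18 tested, 13 of them higher in library 2 and 0 in library 1. C1qa had a TPM of 3.47 and 15.4, and Apoe had 12.2 and 37.6. Not all myeloid genes followed, since the fixed myeloid list lay at the 40.96 percentile of random lists, and Lyz2 (500 and 64 counts), Itgam (22 and 6) and S100a9 (20 and 0) were higher in library 1. RNA of erythroid precursors in library 1 stays open, since the same 16 genes had a median of -1.08 in the large table, between the bounds of -2 and -1 set beforehand, with 10 of the 17 detected in both libraries, and no biological explanation was tested.

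Library 2 had more genes with low values than library 1. Low genes had a TPM under 0.1 in library 1 and under 5 in library 2. Deeper sequencing is argued against, since library 2 held 0.829 of the counts of library 1. RNA of another cell type failed the test written beforehand, but is not excluded. The 10% of low protein-coding genes with the most counts per kilobase held 47.7% of their counts (95% interval 46.1 to 49.4), but the limit of 5 removed genes that such RNA would raise most. Without it the share was 49.2% over 7994 genes (47.3 to 50.8). Both shares were under 50%, the bound set beforehand for counting against such RNA. That bound was set for the share and not for its interval, and the second interval crosses it. Genomic DNA could not be separated from RNA. Counts per kilobase of low protein-coding genes on X were 0.487 of those on autosomes (95% interval 0.390 to 0.590), within the range predicted for DNA of a male. The same genes gave 0.376 in library 1, but from 72.7 counts on X. They were chosen for low values in library 1, so that ratio is a weak control and cannot decide. Y genes held 0.499 counts per kilobase beside 2.38 on X. Low lincRNA and TEC genes gave 0.347 over 85 X genes (0.174 to 0.615), below the range predicted for DNA of a male and with an interval that reaches it. The same genes gave 1.03 in library 1, as predicted for RNA, but from 14.2 counts on X. These genes too were chosen for low values in library 1, so genomic DNA may or may not contribute.

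The 2 gene tables of a library parted at abundant genes. Counting of reads at one position once may contribute, since the slope of log2 small-table count on log2 count per base was -0.234 at more than 4 counts per base in library 2 and -0.404 in library 1, against 0.870 and 0.852 under 0.5 counts per base. Gene length entered only the count per base. With small-table counts also taken per base, the slopes above 4 counts per base were -0.059 in library 2 and -0.189 in library 1. Dropping of reads that map to several genes may contribute as well, since genes with uncertain counts kept a share 0.392 of that of genes with certain counts in library 1 and 0.387 in library 2. In library 1, Gapdh had 64 counts in the small table and 3461 in the large table. No biological explanation was tested.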

How the results depend on the processing

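The 2-fold limit and the subtraction of low counts were chosen after seeing the data. The cause was not tested where none is given. Genes differing between libraries numbered 17040, 9066 with at least 100 counts and 7831 in the small table, where fewer genes were tested, and 9544 with a 2-fold limit. TMM, DESeq2 size factors and no filter stayed within 1.5 times. The correlation of 0.959 was 0.895 with a pseudocount of 0.1, 0.929 at a mean TPM of at least 1, 0.974 in CPM and 0.966 in the small table. The coefficient of variation between the libraries of 0.353 was 1.02 with no filter, 0.356 with library totals and 0.150 from DESeq2. Detected genes numbered 20691 at a TPM of 0.1 instead of 13718, and ranged from 15359 to 19186 in a single library. After subtraction of 4.89 counts per kilobase, library 2 alone had 16684. The number of list genes detected was 211 and ranged from 217 to 221 in a single library. The lists outside the central 95% of random lists were 7, and 6 with a pseudocount of 0.1. The median isoform share of 62.4% was 71.8% by expected counts, and ranged from 58.9% to 69.1% in a single library. Of 215 alternatives for 74 single genes, 205 kept direction and call, 8 lost the call and 2 reversed. Il10, Foxp3 and Top2a lost the call in the small table, Top2a with TMM scaling, and Cd14, Flt3, Top2a and Tyms with DESeq2 size factors. In the small table the log2 ratio of Flt3 was -3.61 instead of 0.59 and that of Tyms -0.046 instead of 0.25. Of 182 called members of the fixed lists tested in both tables, 21 had the opposite sign in the small table, 19 of them higher in library 1 in the large table. Where small-table counts level off, as for B2m (857 and 829 counts), division by the lower total of library 2 raises the ratio. B2m had a log2 ratio of 0.13 there and -0.17 in the large table. Such a change of sign need not mean that a call is unstable. No paired analysis was possible because there was 1 group. Depth limits genes with few counts, since 3 counts are a CPM of 0.113 and 0.136.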

Other observations

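The tests in this part were written before their results were seen, on lists written after the data had been seen. Genes linked to follicular helper cells were higher in library 1, and genes linked to type 1 effector cells were higher in library 2. Among the follicular genes already seen, Sostdc1 had a TPM of 77.8 in library 1 and 2.38 in library 2, Tox2 had 18.2 and 2.10, and Il21 had 12.9 and 0.98. All 8 of these were higher in library 1, with a median log2 ratio of -1.57, and 6 were in the small table. Among the 15 effector genes already seen, all were higher in library 2, with a median of 0.84, and Il18r1 had a TPM of 35.4 and 70.8. These members were partly chosen for the pattern, and 6 and 15 of them stand on the fixed lists.

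A hypothesis is that follicular helper-like cells may make up more of library 1. The 11 follicular genes not looked at before had a median log2 ratio of -0.69, and 9 were higher in library 1 and 0 in library 2. In the small table the median was -0.40, short of the bound of -0.5 set beforehand, with 7 higher in library 1 and 0 in library 2. Among the 9 were Tox, with a TPM of 55.1 and 28.7, Btla with 85.8 and 50.2 and Tbc1d4 with 231 and 143. Detection in both libraries held for 10 of the 11, so most are transcribed in both, and a shift within the population could give the same values. RNA of B cells was not told apart either, since 6 of the 8 fixed B cell genes were higher in library 1, with a median log2 ratio of -0.19 at the 5 percentile of random lists, and Cd79b was 1.53-fold higher. The matching hypothesis for type 1 effector-like cells in library 2 was not settled. The 14 effector genes not looked at before had a median of 0.27, between the bounds of 0.2 and 0.5 set beforehand, with 12 higher in library 2. In the small table the median was 0.18, with 5 higher in library 2. RNA of NK cells was not told apart from that of effector T cells. The NK cell list lay at the 99.05 percentile of random lists, and Gzma had 0 and 11 counts. However, only 4 of its 6 genes were tested, 3 were higher in library 2, and 1 with a ratio below 0 did not pass. Of the 3, Klrk1 (2.32-fold) and Nkg7 stand among the 15 effector genes already seen.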
